A study of Mus musculus with 24 samples.

How the data were processed

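Genomic DNA of 6 mouse Hoxb8-immortalised, GM-CSF-dependent myeloid lines, 3 WT and 3 P95H, was sampled at 4 days each. Per the labels' protocols, cells carried a genome-wide knockout library of 78637 guides, infected at a multiplicity of 0.3 with a target of 500 cells per guide, and were selected with puromycin for 4 days from 48 hours after infection. They then received 400 nM 4-hydroxytamoxifen for 4 days, and days are counted from its start. Guide cassettes were amplified and sequenced as paired reads of 150 bases, days 0 and 11 on lane 2 and days 4 and 18 on lane 3, per the labels.

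The authors deposited a table of read counts per guide and library, which was used as it stands. The submitters' processing notes name fastp 0.20.1, Salmon 0.14.1, STAR 2.7.6a and DESeq2, but not the tool that counted guides. The table holds 78633 targeting guides for 19672 genes, 4 guides for 19638 of them, and 1000 non-targeting guides, and the values are whole numbers without normalization. Guide numbers in the table are not paired with the library's sequences, so no guide sequence is given. Of the genes, 19661 were named by Entrez identifier and 11 kept the symbol of the table. The deposited list of 684 core essential genes, in human symbols, matched 648 genes in the table by symbol without regard to case. Library totals were 22217505 to 33074936 reads. The reads carry no molecular identifiers, so depth covers counting error only.

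Guides with a mean of at least 10 reads over 24 libraries were kept (79150, with 483 left out), and the 19659 genes with at least 2 kept guides were tested on the sum of their guides. Non-targeting guides were put at random (seed 20) into 250 sums of 4, fitted with the genes and left out of the adjustment, to show how often such a sum passes. The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, TMM scaling, two-sided) in R 4.3.3, with the line as a block and a day effect per genotype, Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The contrasts were day 18, 11 or 4 against day 0 in each genotype, and the change in P95H minus the change in WT. Direct comparisons of genotypes used the 6 libraries of a day. The core essential measure was the median log2 CPM (prior count 2) of the guides minus that of non-targeting guides, compared between genotypes by an exact permutation test over 6 lines. Gene lists, 20 fixed ones and the core essential genes, were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated one, adjusted over lists within a contrast. Tables and plots used Python 3.11.15 and matplotlib 3.10.9.

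The design, the gene lists, the alternatives not named below as added later and the rule for named genes were set before the data were examined. The rule takes, per contrast at day 18, the 10 largest falls and 10 largest rises among genes past the threshold with at least 3 kept guides, at least 3 guides in the direction and 3 of 3 lines in the direction (for the difference, no overlap of the line changes). It adds up to 4 members of each list with the smallest p, and 9 genes fixed by name, of which Srsf2, Cdk4, Cdk6, Ccnd3, Trp53, Csf2rb, Jak2 and Myc are reported. Of the 10 largest in each direction, 9 rises are given in WT and in P95H and 10 in the other cases. Single-gene results of a few genes that the rule names were left out of the text after the analysis, without regard to their values. Which of the list members appear in the text was chosen after their values were seen.

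Samples of the same line on other days deviated from their group means together, with r of 0.40 to 0.91 over 36 pairs, and the labels give 1 line per replicate number, so the line is a block.

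The tests were tried on simulated counts in which 100 genes changed 2-fold and 100 changed 4-fold, only in P95H at day 18. For the P95H change edgeR recovered 99% of genes changed 4-fold and 20% of those changed 2-fold, for the genotype difference 72% and 3%, and for the direct comparison at day 18 30% and 1%. It called 7, 10 and 13 of 19459 unchanged genes. Simulated counts held no drift of guides over days, which in the data widened the spread of non-targeting changes from an SD of 0.41 at day 4 to 1.05 at day 18.

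Alternatives were DESeq2 1.42.0, other scalings, no filter, limma on the mean log2 CPM of guides, fry on guides, the most abundant guide left out, fewer libraries, other blocks and each line left out. Alternatives added after the data were seen were the subtraction of reads shared within lane 3, the removal of guides over 0.5% of a library, limma with only day 0 and day 18, p-values rescaled to the non-targeting sums, and the list tests with only day 0 and day 18. The shared share of lane 3 was estimated per library from guides with at least 50000 reads in the lane of which a library of another line held at least 60%. It is the 10th percentile, over these guides, of the library's reads divided by those of the lane's other libraries. Counts that the subtraction would take below 0 were set to 0. Lane 2 had fewer than 10 such guides and was left as it stands. No sample was left out.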

Results

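A pooled CRISPR knockout screen was followed over time in mouse myeloid cells with and without a mutation of the splicing factor Srsf2. The cells were lines immortalised with Hoxb8 and grown in GM-CSF. Of the 6 independently derived lines, 3 carried wild-type Srsf2 (WT) and 3 carried a P95H allele on 1 copy of the gene (P95H), and all carried a tamoxifen-inducible Cre. Guide abundance was counted in genomic DNA of each line at days 0, 4, 11 and 18 after the start of 4-hydroxytamoxifen, which gives 24 libraries. A guide that becomes rarer marks a gene whose loss slowed growth or survival, and a guide that becomes more common marks a gene whose loss was an advantage. Day 0 came after selection for guide-bearing cells, so cutting was already under way. The series title names the cell cycle as a pathway on which the mutant cells depend, and the comparison of the change in P95H with the change in WT addresses that question. Guide counts carry no information on the Srsf2 allele itself, so the genotypes are taken from the labels.

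Libraries held 22217505 to 33074936 reads over 78633 guides against 19672 genes and 1000 non-targeting guides. Guides without a read made up between 0.28% and 1.43% of a library. The Gini index of guide counts, a measure of unevenness, rose in each line from between 0.26 and 0.29 at day 0 to between 0.53 and 0.65 at day 18. Single guides reached large shares late in the culture. Guide 2 against Ralgapb held 7.47% of the reads of WT line 1 at day 18, and guide 4 against Nf1 held 3.44% of P95H line 1. Across genes, the change from day 0 to day 18 correlated between lines with r of 0.59 to 0.60 within P95H, 0.23 to 0.46 within WT and 0.26 to 0.59 between genotypes. Genes are not independent replicates, so these are descriptions of the lines.

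Guides against core essential genes were lost in each line, and 3 P95H lines and WT line 1 lost more than WT lines 2 and 3. Relative to non-targeting guides, the median core essential guide changed from day 0 to day 18 by -2.05 ± 1.01 log2 units in WT (SD, n = 3 lines) and by -3.18 ± 0.20 in P95H (SD, n = 3 lines). The WT values ran from -3.16 in line 1 to -1.19 in line 3. Already at day 0 the core essential level was -1.25 ± 0.39 in WT and -1.87 ± 0.09 in P95H (SD, n = 3 lines each), and the 3 P95H lines lay below the 3 WT lines. Guides against olfactory receptors, which cut genes without a known role in myeloid growth, changed by -0.13 ± 0.08 in WT and -0.15 ± 0.07 in P95H. The exact permutation test gave a two-sided p of 0.2 for the genotype difference of -1.13 in the core essential change, and 0.1 for the difference of -0.62 at day 0. With 3 lines against 3 the exact test cannot go below 0.1. Without WT line 1 the difference in change was -1.69, and without WT line 3 it was -0.70. With the reads shared within lane 3 subtracted it was -2.51, at -2.43 in WT and -4.94 in P95H (exact permutation p of 0.2), and with log2 of CPM plus 1 it was -0.41 (exact permutation p of 0.1). The subtraction stops at 0 reads, so for guides near that floor its values may depend on the prior count of 2.

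**Figure D1:**
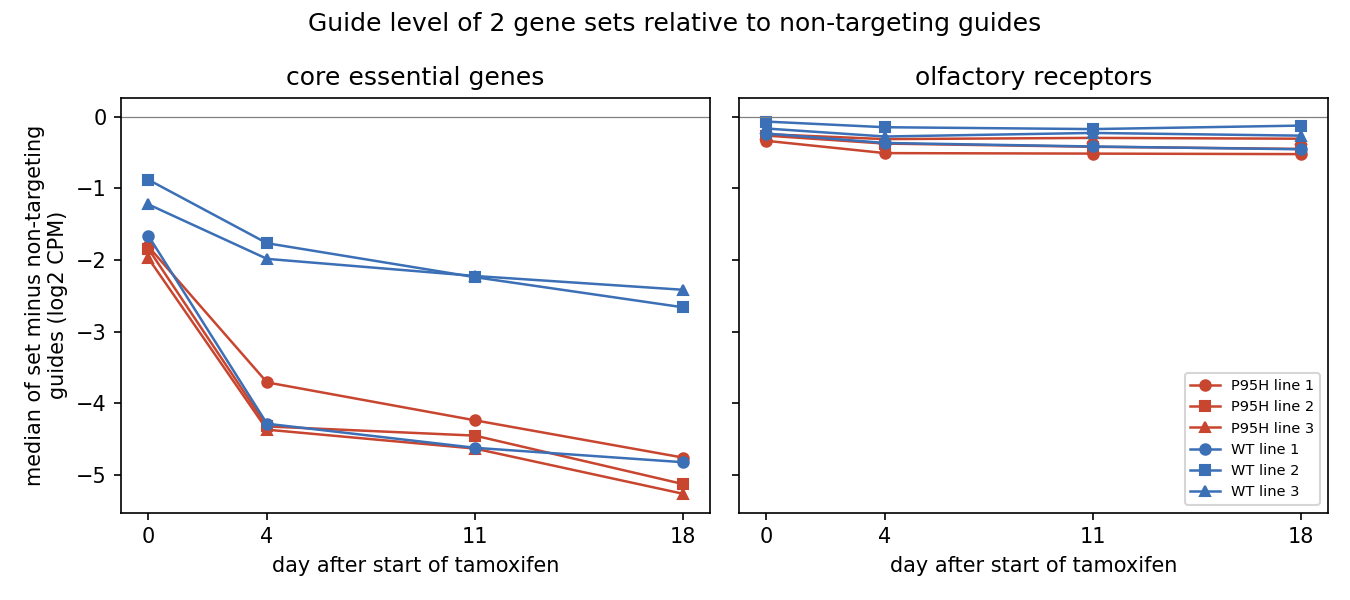
Median log2 CPM of guides against core essential genes (left) and olfactory receptors (right) minus the median of non-targeting guides in the same library (y axis), by day after the start of tamoxifen (x axis). Each joined set of points is 1 line, blue for WT and red for P95H; at day 18 the core essential level runs from -2.41 in WT line 3 to -5.26 in P95H line 3, with WT line 1 at -4.82.

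In WT cells 1829 genes fell and 1514 rose by day 18. The steepest falls among genes that met the naming rule were Rps15a at -7.29 ± 0.94 log2 units, the histone gene H3c4 at -7.03 ± 1.09, and H3c10 at -6.12 ± 1.03 (SE, n = 3 lines). For these and all later fitted changes and genotype differences, the SE does not come from the spread between 3 lines. It is the absolute log2 change divided by the square root of the F statistic from the fit of all 24 libraries. That fit holds 1 spread for all days, while non-targeting guides spread more widely at day 18, so these SEs may be too small. Hmgb1, a chromatin protein, fell by 4.87 ± 0.57 and Scd2, a fatty acid desaturase, fell by 4.83 ± 0.50, each with 4 of 4 guides. The naming rule itself asks for 3 of 3 lines and at least 3 guides in the direction. Rpl23 (-4.97), Rps15 (-4.80), Tmem164 (-4.65), Oip5 (-4.64) and Fau (-4.55) complete the 10 steepest. Over 21 settings Rps15a in WT ran from -7.98 to -3.63, H3c4 from -8.51 to -3.11 and H3c10 from -8.20 to -1.82. Among rises, Ralgapb reached 5.49 ± 1.32, the RAS inhibitor Nf1 3.67 ± 1.11 and the repressor Cic 3.54 ± 0.72. The call was lost in 9 of 21 settings for Nf1 (smallest for day 18 against day 4, where Nf1 in WT had an edgeR adjusted p = 0.455), in 4 for Ralgapb (2.45 to 8.03) and in 3 for Cic (2.42 to 4.38). Sfmbt1 (3.33), Ptprc (3.16), B4galt1 (2.79), Tfpt (2.78), Fbh1 (2.73) and Ggnbp2 (2.70) followed, of which Fbh1 had 3 of 4 guides higher and the others 4 of 4. Guide 2 against Fbh1 had 83.1% of its lane 3 reads in WT line 1 at day 18. Fbh1 in WT was at 0.65 with the most abundant guide left out and at 0.74 without WT line 1 (edgeR adjusted p = 0.0332 and 0.0482), and the call was lost in 5 of 21 settings.

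Of 648 core essential genes 309 fell and 3 rose in WT (394 and 4 adjusted over the list alone; camera adjusted p = 0.0563 with an estimated correlation). Guides fell for 56 of 83 cytosolic ribosomal proteins (67 adjusted over the list alone) and for 45 of 76 mitochondrial ribosomal proteins (53 adjusted over the list alone), such as Rpl37 at -3.89 and Mrps25 at -3.60. Proteasome guides fell for 17 of 39 subunits (20 adjusted over the list alone), Psmd4 at -4.07 and Psmc5 at -2.83 among them. In the core spliceosome 25 of 55 genes fell and 1 rose (33 and 1 adjusted over the list alone), with Phf5a at -3.95, Sf3b3 at -3.80 and Sf1 at -2.64. Of 38 SR proteins and splicing regulators 12 fell (12 adjusted over the list alone), with Srsf3 at -3.14 and Mbnl1 at -3.12. The mitochondrial ribosome and the SR protein list passed camera with a preset correlation and also with an estimated one (camera adjusted p = 0.0232 with an estimated correlation for both). For the cytosolic ribosome and the spliceosome the adjusted p was 0.0563 with an estimated correlation, and for the proteasome the adjusted p was 0.0615 with an estimated correlation. At day 4 and day 11 these lists passed in WT, with camera adjusted p of 0.00298 and 0.0224 for the cytosolic ribosome and core essential genes, 0.00547 and 0.0224 for the spliceosome and 0.0126 and 0.0224 for the proteasome, each with an estimated correlation.

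Of 44 replication proteins 23 fell in WT (28 adjusted over the list alone), such as the sliding clamp Pcna at -3.38 and the helicase factor Cdc45 at -2.60. Of 39 genes of G2/M and mitosis 16 fell (19 adjusted over the list alone), with Cdc23 at -4.52 and Mad2l1 at -2.93. Among 20 G1/S cyclins, CDKs and activators 6 fell and 1 rose (12 and 2 adjusted over the list alone), with E2f4 at -2.52 ± 0.31, Cdk7 at -2.45 ± 0.50 and the D-type cyclin Ccnd3 at -2.12 ± 0.44. In GM-CSF receptor, JAK-STAT and RAS-MAPK signalling 10 of 27 fell and 2 rose (12 and 2 adjusted over the list alone), with Ptpn11 at -3.06, the receptor chains Csf2ra at -2.80 and Csf2rb at -1.64, and Gab2 at -2.49. Of 27 myeloid transcription factors and regulators 9 fell and 1 rose (11 and 1 adjusted over the list alone), with Hoxb8 at -3.85 ± 0.70, Cbfb at -2.78, Ikzf1 at -2.53 and Myb at -2.16. Hoxb8 guides could also cut the immortalising copy. The adjusted p of camera was 0.0563 with an estimated correlation for replication, mitosis, GM-CSF signalling and the myeloid list, and 0.103 with an estimated correlation for the G1/S list.

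The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 3343 of 19659 genes in WT at day 18, 1829 lower and 1514 higher. Of 250 sums of 4 non-targeting guides, 33 (13.2%) passed the same unadjusted p, 30 of them upward. The call of a rise alone therefore does not set a gene apart from guides that cut nothing. Among the non-targeting sums that passed, rises reached 2.24 log2 units. With only day 0 and day 18 libraries 26 genes passed, without the line as a replicate block 363, and within lane 3, day 18 against day 4, 457. By limma with only day 0 and day 18 libraries 3514 passed, 3386 of them lower, and 1809 of the 3343 were among them. Limma used the mean log2 CPM of guides in place of the sum, and with all libraries it called 6595 lower and 463 higher. Without WT line 1 1847 passed. With library totals or non-targeting totals as the scale, calls turned mostly downward, at 5041 lower and 395 higher and at 6559 lower and 329 higher, with the median of all genes shifted by -0.38 and -0.46 log2 units.

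In P95H cells 2732 genes fell and 1756 rose by day 18. H3c4 changed by -7.72 ± 1.21 log2 units, Rps15a by -6.55 ± 0.91 and H3c10 by -6.18 ± 1.05. Over 21 settings these ran from -10.6 to -1.82, from -7.17 to -2.18 and from -7.44 to -3.13, so size and order depend on the setting. Umps, the enzyme that completes UMP synthesis, changed by -6.10 ± 0.48, the mitochondrial asparaginyl-tRNA synthetase Nars2 by -5.89 ± 0.64, and Ptpn11, a phosphatase that relays receptor signals to RAS, by -5.79 ± 0.63. Gm5148 (-6.16), Rpl15 (-6.01), Rpl4 (-5.87) and Rpl17 (-5.87) were the others among the 10 steepest. Guides against Nf1 rose by 5.64 ± 1.24, Ggnbp2 by 4.57 ± 0.66 and Ralgapb by 4.38 ± 1.18. In P95H the call of Nf1 was lost in 5 of 21 settings (3.38 to 6.94) and that of Ralgapb in 7 (1.28 to 4.80). Uchl5 (3.81), Cic (3.34), Tfpt (2.99), Sfmbt1 (2.99), the cell cycle repressor E2f8 (2.97) and Ptprc (2.76) followed, all with 4 of 4 guides higher. The p53 gene Trp53 rose by 2.49 ± 0.53. In the GRCm38 build Nf1 (Entrez gene 18015) lies on chromosome 11 from 79339590 to 79581609, Umps (22247) on chromosome 16 from 33954782 to 33967038 and Cdk6 (12571) on chromosome 5 from 3341004 to 3531008.

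Of 11 apoptosis inhibitors 5 fell in P95H (5 adjusted over the list alone), with Mcl1 at -3.92 ± 0.58 and Bcl2l1 at -2.61 ± 0.40 (camera adjusted p = 0.0491 with an estimated correlation). Of 19 apoptosis effectors 8 rose and 4 fell (9 and 4 adjusted over the list alone), with the pore-forming Bax at 1.79 ± 0.21 and the BH3-only gene Bbc3 at 1.73 ± 0.31, whereas the death receptor genes Fadd at -2.94 and Casp8 at -2.37 fell (camera adjusted p = 0.114 with an estimated correlation). In the p53 pathway 6 of 20 rose and 5 fell (8 and 5 adjusted over the list alone), the p53 inhibitors Mdm4 at -2.20 ± 0.41 and Ppm1d at -3.05 ± 0.54 among those lower. That list did not pass camera (adjusted p = 0.228, and 0.247 with an estimated correlation), and its median of 0.34 and mean of -0.10 differ in sign.

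Of 648 core essential genes 517 fell in P95H (568 and 1 higher adjusted over the list alone; camera adjusted p = 0.0112 with an estimated correlation). Guides fell for 72 of 83 cytosolic ribosomal proteins (77 adjusted over the list alone), 65 of 76 mitochondrial ones (70), 45 of 55 spliceosome genes (50) and 27 of 39 proteasome subunits (28), where each number in parentheses is adjusted over the list alone. Examples are Rpl32 at -5.78, Mrps34 at -3.97, Snrpe at -3.47 and Psmc6 at -3.65. Of 44 replication proteins 35 fell (39 adjusted over the list alone), with Rfc2 at -4.87 and Mcm4 at -3.61, and of 39 mitotic genes 26 fell (29 adjusted over the list alone), with Plk1 at -4.10 and Espl1 at -3.99. In replication stress signalling 18 of 23 fell (18 adjusted over the list alone), Pkmyt1 at -4.06 and Hus1 at -3.48 among them. Among G1/S cyclins, CDKs and activators 10 of 20 fell and 2 rose (10 and 2 adjusted over the list alone), with Cdk6 at -3.91 ± 0.54, Cdk7 at -3.65 and Skp1 at -3.11 lower, and Cdk4 at 0.80 ± 0.28 higher (edgeR adjusted p = 0.0441). That call of Cdk4 in P95H was lost in 13 of 21 other settings, where it ran from 0.29 to 1.14, and 1 of 4 guides passed alone. The camera adjusted p with an estimated correlation was 0.0112 for the spliceosome, 0.0187 for the cytosolic ribosome, proteasome, replication and mitosis lists, 0.0202 for replication stress and 0.00330 for the mitochondrial ribosome, and the G1/S list had an adjusted p of 0.124 with an estimated correlation.

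Of 27 signalling genes 12 fell and 1 rose in P95H (14 and 2 adjusted over the list alone), with Grb2 at -4.31, the kinase Jak2 at -3.28 ± 0.61, Gab2 at -2.82 and Csf2rb at -2.55 (camera adjusted p = 0.0202 with an estimated correlation). Of 27 myeloid regulators 10 fell and 2 rose (12 and 3 adjusted over the list alone), with Hoxb8 at -3.77, Zeb2 at -2.80, Runx1 at -2.79 and Spi1 at -2.38 (camera adjusted p = 0.124 with an estimated correlation). Myc, the growth-promoting transcription factor, fell by 4.12 ± 0.58 in P95H and by 2.85 ± 0.53 in WT. Of the 1829 genes lower in WT, 1243 were also lower in P95H, where independent lists of these sizes would share 254, and 223 of the genes higher in WT were higher in P95H, against 135. In the opposite direction, 24 genes lower in WT were higher in P95H and 35 higher in WT were lower. The genotypes shared guides and sequencing lanes, so their lists are not independent and the excess is only a description.

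In P95H the edgeR quasi-likelihood test called 4488 genes, 2732 lower and 1756 higher, and 26 of 250 non-targeting sums (10.4%) passed the same p, 25 of them upward, so the rises in P95H carry the same doubt as those in WT. With only day 0 and day 18 libraries 1223 passed, 1178 of them lower, without the line as a replicate block 1524, within lane 3 1016, and without P95H line 2 2846. By limma with only day 0 and day 18 libraries 3876 passed, 3702 of them lower, and 2772 of the 4488 were among them. With all libraries limma called 5646 lower and 605 higher in P95H. Scaling to library totals gave 4748 lower and 440 higher and to non-targeting totals 5285 lower and 388 higher, with the median of all genes shifted by -0.34 and -0.38 log2 units.

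Among the 10 largest genotype differences downward, where guides changed further downward in P95H, the mitochondrial RNA polymerase Polrmt differed by -3.39 ± 0.58 log2 units, Coa6, which helps to assemble cytochrome c oxidase, by -3.26 ± 0.47, the ATP synthase subunit Atp5a1 by -3.21 ± 0.69 and Mrpl39 by -3.16 ± 0.57 (SE, n = 3 lines per genotype). Dhps, the first enzyme of hypusine synthesis, differed by -3.56 ± 0.76 and Ciao1, which delivers iron-sulphur clusters, by -3.31 ± 0.64. H2bc12 (-4.11), H4c18 (-3.36), Rps27a (-3.23) and the U2 snRNP subunit Sf3b6 (-3.19) complete the list. Upward, the histone methyltransferase Dot1l differed by 2.66 ± 0.57, Psme3 by 2.32 ± 0.37 and the JAK-STAT inhibitor Cish by 2.21 ± 0.59. Ces2f (2.16), Olfr730 (2.14), Olfr1193 (2.03), Zfp3 (2.00), Cpeb1 (1.98), Ms4a3 (1.92) and Lcn4 (1.91) followed, among them olfactory receptors, for which no growth role is known. Each of these 20 calls was lost in some of 23 settings, from 4 for Cpeb1 to 14 for Dhps, H4c18 and Olfr1193, with 13 for H2bc12 and Rps27a and 7 for Ciao1.

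For some named genes the sum and most of the guides moved in opposite directions. Sf3b6 rose in the WT sum by 1.62 although 3 of 4 guides were lower there. Psme3 rose by 1.10 in the P95H sum with 3 of 4 guides lower. Atp2a2 had a WT sum of 1.08 with 3 of 4 guides lower, and its difference was -3.13 ± 0.51. Guides against histone, ribosomal protein and predicted genes such as H3c4, H2bc12, Rps27a and Gm5148 may match near-identical copies elsewhere, so the gene behind their loss is uncertain.

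By list, 11 of 21 lists differed between genotypes at day 18 in camera with a preset correlation and 0 with an estimated one (smallest adjusted p = 0.140 with an estimated correlation). Of 648 core essential genes 35 were lower in P95H (49 and 1 higher adjusted over the list alone; list adjusted p = 3.31e-13, and adjusted p = 0.391 with an estimated correlation), and of 83 cytosolic ribosomal proteins 1, Rps27a (3 adjusted over the list alone; 6.75e-07, and adjusted p = 0.391 with an estimated correlation). For the mitochondrial ribosome 8 of 76 members passed, all lower in P95H (17 and 1 higher adjusted over the list alone), with Mrpl16 at -2.78 ± 0.45 (list adjusted p = 7.46e-09, and adjusted p = 0.258 with an estimated correlation). In the core spliceosome 3 of 55 were lower (3 adjusted over the list alone), with Zmat2 at -2.03 ± 0.39 and Sf3b6 as above (1.74e-07, and adjusted p = 0.287 with an estimated correlation). Among replication stress genes 2 of 23 were lower (2 adjusted over the list alone), namely Pkmyt1 at -2.42 ± 0.56, an inhibitory kinase of the mitotic CDK, and Topbp1 at -1.69 ± 0.41 (0.00367, and adjusted p = 0.391 with an estimated correlation). For complex I 2 of 41 were lower and 1 higher (5 and 1 adjusted over the list alone), with Ndufaf7 at -2.79 ± 0.45 and Ndufa2 at 1.73 ± 0.43 (0.00416, and adjusted p = 0.460 with an estimated correlation). Apoptosis effectors had 1 of 19 higher (4 adjusted over the list alone), Bax at 1.15 ± 0.29 (0.0207, and adjusted p = 0.258 with an estimated correlation), and apoptosis inhibitors 1 of 11 lower (3 adjusted over the list alone), Birc2 at -0.98 ± 0.26 (0.0157, and adjusted p = 0.258 with an estimated correlation). Birc2 rose by 1.28 in WT and was at 0.30 in P95H (edgeR adjusted p = 0.27). Its difference thus reflects a rise in WT, not a fall in P95H. Proteasome subunits had 1 of 39 lower (2 adjusted over the list alone), Psmc3 at -2.88 ± 0.55 (0.000913, and adjusted p = 0.391 with an estimated correlation). Lists that did not pass held the splicing regulators Hnrnpu at -2.97 ± 0.64 and Srsf9 at -0.92 ± 0.24, 2 of 38 (3 adjusted over the list alone), and the p53 inhibitor Mdm4 at -2.59 ± 0.57. Of the list members named here, the call was lost in 4 of 23 settings for Ndufaf7, 13 for Pkmyt1 and Mdm4, 14 for Topbp1 and Ndufa2, 12 for Bax and Hnrnpu, and 16 for Birc2 and Srsf9.

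The G1/S list, which bears on the question in the series title, did not pass in the difference, with camera adjusted p = 0.725 and 0 of 20 members past the edgeR test over all genes (1 lower and 1 higher adjusted over the list alone). Cdk6 changed by -1.99 ± 0.50 in WT and -3.91 ± 0.54 in P95H, a difference of -1.91 ± 0.70 (edgeR adjusted p = 0.122) in which 2 of 4 guides lay lower and 2 higher. Its line values were -3.53, -1.31 and -0.86 in WT and -2.81, -4.48 and -4.50 in P95H. Cdk4 had -0.59 ± 0.28 in WT and 0.80 ± 0.28 in P95H, a difference of 1.39 ± 0.39 (edgeR adjusted p = 0.0560). The difference passed in 3 of 23 settings for Cdk4 and in 2 for Cdk6, with DESeq2 for both (smallest adjusted p 0.0102 for Cdk4 with DESeq2 and 0.0110 for Cdk6 with edgeR without WT line 1). For Ccnd3 the difference was -0.40 ± 0.61. Of the 44 replication and 39 mitotic genes 0 passed edgeR over all genes (0 and 4 adjusted over the list alone), with list medians of -0.83 and -0.81 and camera adjusted p of 0.000638 and 0.00367 (adjusted p = 0.391 with an estimated correlation for both).

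Srsf2 guides themselves disagreed. Guide 2 changed by -4.16 in WT and -6.06 in P95H and guide 3 by -3.12 and -4.36, whereas guide 1 changed by -0.10 and 1.58 and guide 4 by 0.14 and -0.77. The summed change was -0.43 ± 0.39 in WT and 0.78 ± 0.39 in P95H, neither past the edgeR test, and by limma on the mean of the guides it was -1.91 in P95H. In WT a fall passed in 2 of 21 settings, with values down to -1.65 over the settings. The genotype difference of Srsf2 passed in none of 23. Other genes fixed in advance had differences of -1.58 ± 0.81 (Jak2), -1.27 ± 0.74 (Myc), -0.91 ± 0.64 (Csf2rb) and 1.22 ± 0.73 (Trp53), with edgeR adjusted p between 0.272 and 0.426.

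**Figure D2:**
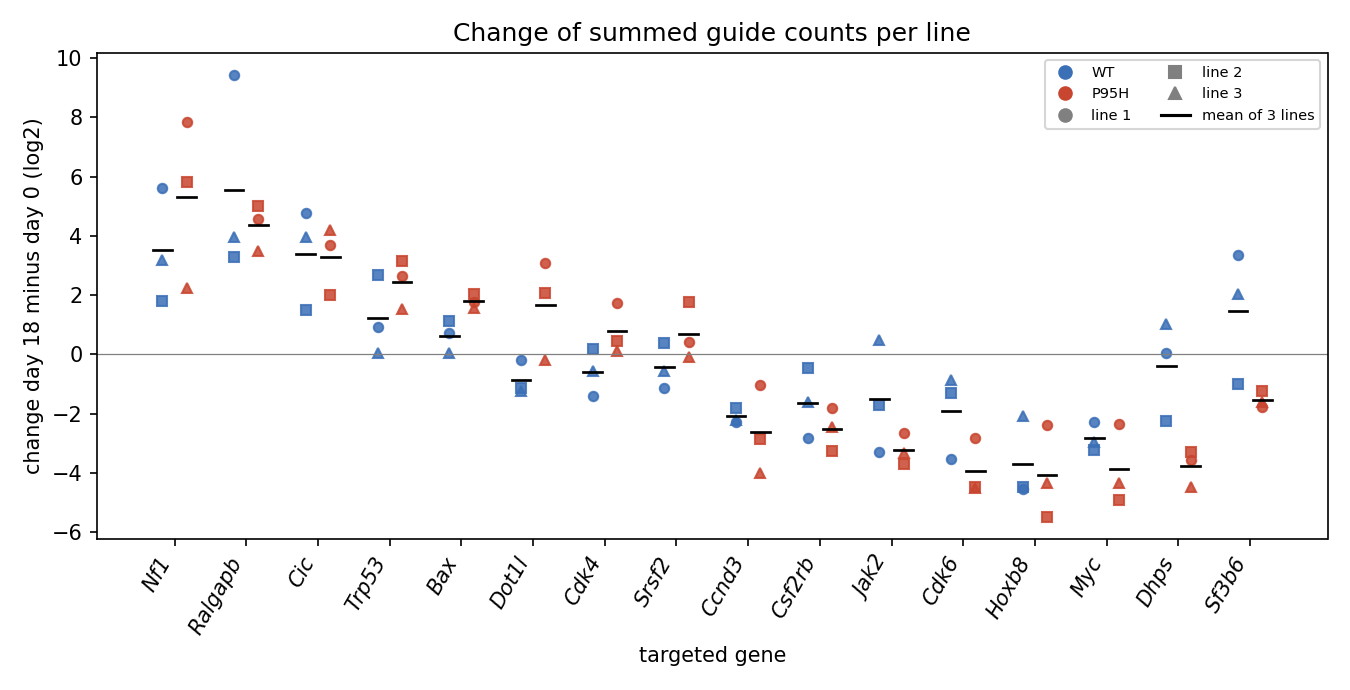
Change of the summed guide counts of 16 genes from day 0 to day 18 in log2 units (y axis) for each gene (x axis), with 1 point per line (blue WT, red P95H, shape for the line number) and a black bar at the mean of 3 lines. Nf1 in P95H spans 2.25 to 7.83, and Cdk6 spans -3.53 to -0.86 in WT and -4.50 to -2.81 in P95H.

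For the difference in change the edgeR quasi-likelihood test called 674 genes (3.43%), 400 lower and 274 higher in P95H. Of 250 non-targeting sums, 4 (1.6%) passed the same p. That share is not small beside the share of genes, so a sizeable part of the 674 calls may be false. Of 1078 olfactory receptors, for which no growth role is known, 13 were called lower and 20 higher in P95H. They were thus called about as often as genes at large, so the false part may be larger than the non-targeting sums show. Line changes did not overlap between genotypes for 10.55% of genes, where chance gives 10% for 3 against 3. With only day 0 and day 18 libraries edgeR called 0 genes (1057 at an unadjusted p under 0.05) and limma called 0 (1280), and without the line as a replicate block 3 passed. DESeq2 called 1896, and within lane 3 60 passed. With the most abundant guide of each gene left out 504 passed, but only 198 of the 674 were among them. Without WT line 1 1360 passed, without P95H line 2 256 and without P95H line 3 382. With non-targeting totals as the scale 57.9% of the calls were upward, against 40.7%.

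**Figure D3:**
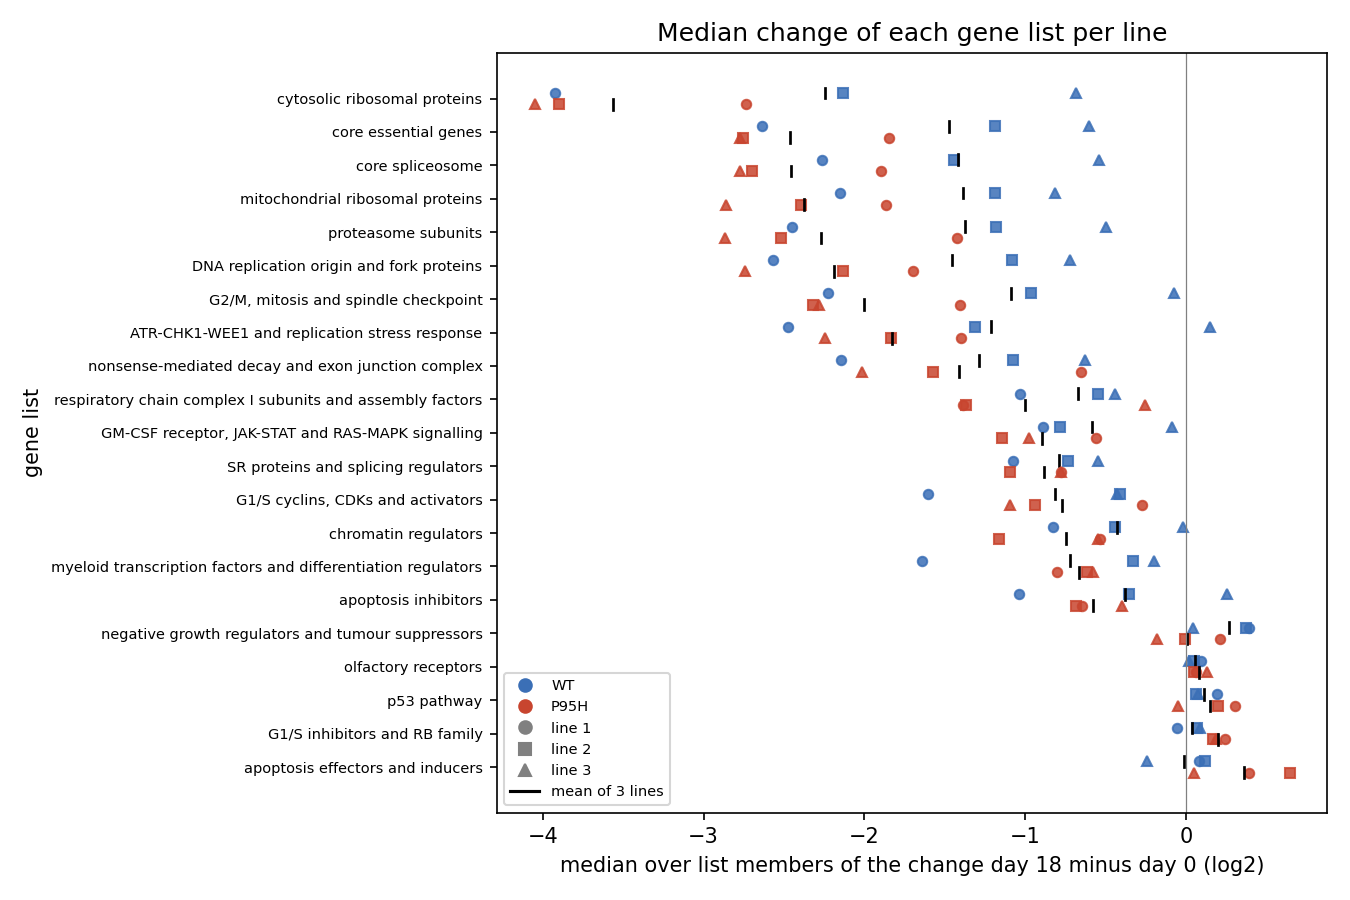
Median over the members of each gene list (y axis) of the change from day 0 to day 18 in log2 units (x axis), with 1 point per line (blue WT, red P95H, shape for the line number) and a black bar at the mean of 3 lines. The mean core spliceosome value is -1.42 in WT and -2.45 in P95H, and for olfactory receptors it is 0.05 and 0.08.

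At earlier days more genes passed in P95H than in WT, although the difference itself called none. By day 4 edgeR called 693 genes in P95H, all lower, Umps at -3.79 and Myc at -3.29 among them, and 0 in WT (1091 at an unadjusted p under 0.05, with DESeq2 at 366 and limma at 1256). By day 11, on the same lane as day 0, it called 1767 genes in P95H, 1645 of them lower, and 252 in WT, 222 of them lower. Scd2 had changed by -3.20 in WT and -3.04 in P95H at day 11, and Hmgb1 by -2.42 and -3.34. The genotype difference gave 0 genes at day 4 (122 at an unadjusted p under 0.05, DESeq2 1, limma 0) and 0 at day 11 (995, DESeq2 42, limma 0) with edgeR. By list, the genotype difference at day 4 passed camera for 13 of 21 lists, of which 5 passed also with an estimated correlation. These 5 were lower in P95H, namely core essential genes (median -0.60), the core spliceosome (-0.72), SR proteins and splicing regulators (-0.20) and mitochondrial ribosomal proteins (-0.52), each with a camera adjusted p = 0.0296 with an estimated correlation, and replication proteins (-0.63, adjusted p = 0.0308 with an estimated correlation). Olfactory receptors had a camera adjusted p of 0.219, and adjusted p = 0.0308 with an estimated correlation, at a median of 0.02, but relative to non-targeting guides their difference was -0.01 (exact permutation p of 1). By line, the core essential change at day 4 differed by -0.83 (exact permutation p of 0.4), and WT line 1 at -2.63 lay below the P95H lines at -1.90, -2.48 and -2.40. In these 6 lists no member passed edgeR over all genes or adjusted over the list alone. At day 11 the difference passed for 12 lists, and for none with an estimated correlation (smallest adjusted p = 0.150 with an estimated correlation). Without the line as a replicate block, P95H had 1 gene at day 4 and 83 at day 11 and WT had 0 at day 11 (751 at an unadjusted p under 0.05 with edgeR).

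Compared directly at day 18, P95H lines had fewer guides than WT lines for the proteasome ATPase gene Psmc3 and the transcription factor gene Gtf2e1, at -3.70 and -3.37 log2 units (edgeR adjusted p = 0.0386 for both, n = 3 lines per genotype). Both genes were named after their values were seen. With DESeq2 357 genes passed. Without WT lines 1, 2 and 3 in turn edgeR called 319, 99 and 14, and without P95H lines 1, 2 and 3 it called 0 each time (1910, 1387 and 1670 at an unadjusted p under 0.05). Core essential genes were lower in P95H for 571 of 648 genes at day 18, with a median of -1.71. At day 0, before tamoxifen, they were already lower for 623 of 648, with a median of -0.48. The direct day 0 comparison called 0 genes with edgeR (1797 at an unadjusted p under 0.05), 0 with limma and 21 with DESeq2, and without WT line 1 519 with edgeR.

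A measured feature of the sequencing bears on days 4 and 18, which shared lane 3, while days 0 and 11 shared lane 2. Guide 2 against Ralgapb stood at 91.1 to 111 CPM at day 0 in the 6 lines, at 986 to 1242 at day 4, and back at 112 to 344 at day 11 in the 5 lines other than WT line 1. Reads of the guides that a single library dominated appeared in each of the 12 lane 3 libraries. Relative to the reads of those guides in the lane's other libraries, the 10th percentile over guides was 0.76% to 1.22% by library. The median over guides was 1.06% to 1.75%. After subtraction of the share at the 10th percentile, P95H had 10 genes at day 4 in place of 693 and WT had 2124 at day 18 in place of 3343. The 693 genes were all still lower at day 4, 663 of them further than before, with a median of -2.63 in place of -2.28. The subtraction takes reads from day 4 and none from day 0. Deeper falls of depleted genes therefore follow from the subtraction itself and do not bear on whether the calls hold. For Ralgapb at day 18, guide 2 went from 950 and 961 CPM to 44.4 and 0 in WT lines 2 and 3, guide 3 from 349 and 809 to 111 and 561 (43.0 and 48.4 at day 0) and guide 1 from 71.8 and 204 to 0 and 130 (20.5 and 24.4 at day 0). In P95H lines 1 and 2 guide 2 of Ralgapb went from 1648 and 1845 CPM to 783 and 945. Guide 4 against Nf1 went from 449 to 42.1 CPM in WT line 2 (118 at day 0) and from 428 to 54.2 in P95H line 3 (90.6 at day 0), and remained above day 0 in WT lines 1 and 3 (340 and 213, against 54.2 and 64.7) and P95H lines 1 and 2 (34275 and 4549, against 100 and 108). With the subtraction, Nf1 in WT was at 2.71 and did not pass (edgeR adjusted p = 0.226), and Nf1 in P95H passed at 5.27 (0.0254). Ralgapb in WT was at 4.37 (edgeR adjusted p = 0.0632) and Ralgapb in P95H at 3.47 (0.0683), and neither passed. Both genotypes shared each lane on a given day.

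**Figure D4:**
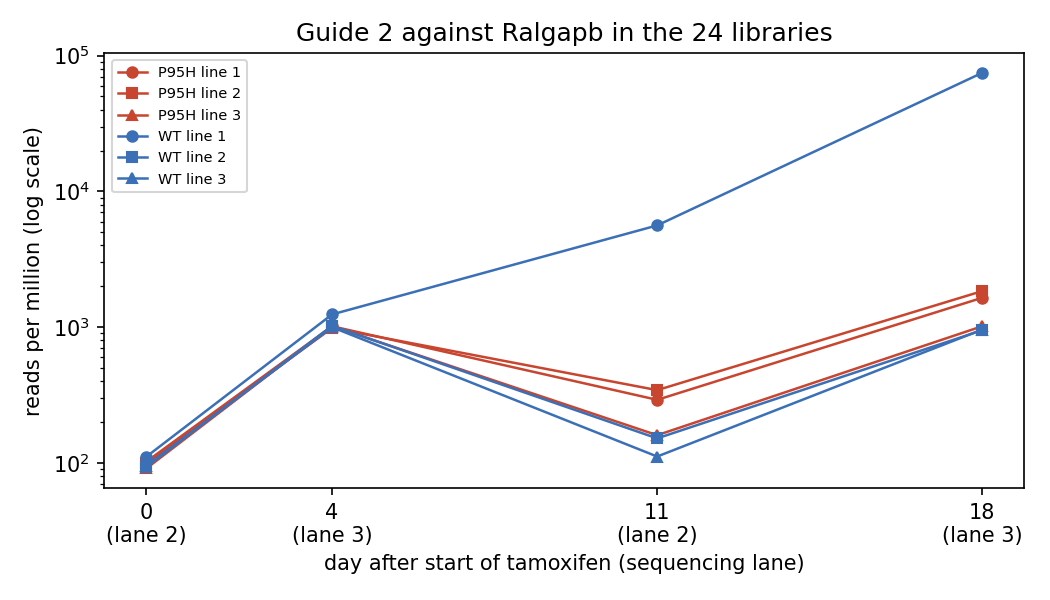
CPM (y axis, log scale) of guide 2 against Ralgapb in the 24 libraries by day and sequencing lane (x axis), with 1 joined set of points per line, blue for WT and red for P95H. At day 4 the 6 lines lie between 986 and 1242, and at day 18 WT line 1 reaches 74737 while the others lie between 950 and 1845.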

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

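Results are listed here because a test of the difference itself set the genotypes apart. The tests of explanations below, and the count of other splits, were chosen after the results were seen.

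The change from day 0 to day 18 differed between P95H and WT for 674 genes. Of the named genes, those lower in P95H were H2bc12 (-4.11), Dhps (-3.56), Polrmt (-3.39), H4c18 (-3.36), Ciao1 (-3.31), Coa6 (-3.26), Rps27a (-3.23), Atp5a1 (-3.21), Sf3b6 (-3.19), Mrpl39 (-3.16), Atp2a2 (-3.13), Umps (-3.08), Hnrnpu (-2.97), Cox11 (-2.94), Psmc3 (-2.88), Ndufaf7 (-2.79), Mrpl16 (-2.78), Mdm4 (-2.59), Pkmyt1 (-2.42), Zmat2 (-2.03), Ccnc (-1.96), Topbp1 (-1.69), Birc2 (-0.98), Cdkn2d (-0.94) and Srsf9 (-0.92). The olfactory receptor Olfr103 (-1.25) was also lower. Those higher were Dot1l (2.66), Psme3 (2.32), Cish (2.21), Ces2f (2.16), Olfr730 (2.14), Olfr1193 (2.03), Zfp3 (2.00), Cpeb1 (1.98), Ms4a3 (1.92), Lcn4 (1.91), Ndufa2 (1.73) and Bax (1.15). Some differences came from a change in WT and not in P95H. Birc2, Cdkn2d and Olfr103 rose in WT, by 1.28, 0.76 and 1.35, and were at 0.30, -0.17 and 0.10 in P95H, where none passed. Ndufa2 fell in WT by 2.38 and was at -0.65 in P95H, where it did not pass.

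By camera with a preset correlation 11 lists differed. The adjusted p was 3.31e-13 for core essential genes, 7.46e-09 for mitochondrial ribosomal proteins, 1.74e-07 for the core spliceosome, 6.75e-07 for cytosolic ribosomal proteins, 0.000638 for replication, 0.000913 for the proteasome, 0.00367 for both mitosis and replication stress, 0.00416 for complex I, 0.0157 for apoptosis inhibitors and 0.0207 for apoptosis effectors. None passed with an estimated correlation at day 18. At day 4, 5 of the 13 lists past the preset correlation did, with a smallest camera adjusted p of 0.0296, while by line the core essential change then differed with an exact permutation p of 0.4. The calls of single genes were lost in some settings each, in 18 of 23 for Cdkn2d.

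There are 10 ways to split 6 lines 3 against 3, too few for a share under 0.05. For the genotype difference 3 of the 10 splits gave at least the 674 genes of the real one, and the highest other gave 992. At day 0 the real split called none with edgeR, so each of the 10 reaches it whatever the data hold and the count says nothing (highest other 8). At day 18 2 gave at least the real 2 (highest other 5). For the change over time the line pairs the samples, so the real split is compared with those that part all 3 pairs, 4 with the real one, which is too few for a share under 0.05. In WT the real split called 3343 genes and the highest other 693, in a split that exchanged the days of line 3. In P95H the real split called 4488 and the other splits none with edgeR. The remaining 6 splits part only 1 pair, keep both days of the other 2 lines together and called none in either genotype.

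Guides that 1 line dominated at day 18 were raised in each library of lane 3. Reads assigned to the wrong library within a lane would lift other lines at day 4 but not at day 11, and day 4 lay above both day 0 and day 11 in 98.3% of 60 pairs of guide and line. The pairs came from the 12 guides of which 1 library held at least 80% of the lane 3 reads, each in the other lines. They share guides and lines, so they are not independent. Expansion of the same guides in each line would keep day 11 at or above day 4, but the median log2 ratio of day 11 to day 4 was -1.52. A shared share of reads is therefore the likely source of the day 4 rises, and it may also hold up depleted guides at days 4 and 18.

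Core essential guides were lower in P95H than in WT before tamoxifen. A difference in depth is unlikely, since with all libraries thinned to the smallest total the difference was -0.61 against -0.62. Earlier or more cutting in the P95H lines may add to it, as olfactory receptor guides also differed by -0.13, but the exact permutation p of 0.1 is the smallest 6 lines can give. A genotype effect before induction and the history of the lines cannot be told apart, with an exact p of 0.1, and WT line 1 lay near the P95H lines at -1.66.

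Sums of non-targeting guides passed the day 18 test more often than the 5% that chance gives, at 25.2% in WT, 26.8% in P95H and 18% in the difference for an unadjusted p under 0.05. A spread that grows over the days but is fitted as constant could produce this, and with only day 0 and day 18 libraries the highest of the 3 shares was 6.8%. The scaling of the libraries is unlikely to be the whole cause, since with non-targeting totals the lowest share was 19.6%. A few guides that take many reads are also unlikely, since without guides over 0.5% of a library the lowest share was 18%. Calls at day 18 with all days in the fit may therefore hold more false ones than the adjusted p states.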

How the results depend on the processing

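Alternatives named in processing as added later were chosen after the data were seen. Among named genes with a call in either fit, only Srsf2 in P95H changed sign, from 0.78 in edgeR, where it did not pass, to -1.91 by limma (adjusted p = 0.000862) and -1.90 by limma with only day 0 and day 18 (0.00128). The cause of each change below was not tested unless stated. For the change in WT (3343), counts were 6888 with non-targeting totals, 5436 with library totals, 7058 with limma, 6524 with fry, 26 with only day 0 and day 18 in edgeR (3514 by limma), 457 for day 18 against day 4, 363 with no replicate block, 2124 with reads shared within lane 3 subtracted and 0 with rescaled p-values in edgeR (1375 at an unadjusted p under 0.05, DESeq2 without rescaling 4563). With 1 line left out they ran from 1847 to 3362. For P95H (4488), counts were 1223 with only day 0 and day 18 in edgeR (3876 by limma), 1016 for day 18 against day 4, 1524 with no replicate block and 0 with rescaled p-values in edgeR (1861 at an unadjusted p under 0.05, DESeq2 without rescaling 5570), and 2846 to 4589 with 1 line left out. For the difference (674), counts were 1896 with DESeq2, 0 with only day 0 and day 18 in edgeR (1057 at an unadjusted p under 0.05), 60 for day 18 against day 4, 3 with no replicate block, 308 with a replicate block across genotypes, 183 for the average of days 11 and 18, 0 by limma with only day 0 and day 18 (1280), 0 with rescaled p-values (1405), and 256 to 1360 with 1 line left out. Similar counts did not always hold the same genes. With the most abundant guide left out 504 genes passed for the difference, but only 198 of the 674 were among them. With limma 522 passed (288 of the 674 among them) and without WT line 3 471 (261). With non-targeting totals 668 passed, 555 of the 674 among them. Samples that share a replicate number across genotypes share only the number, since they did not deviate together (r from -0.03 to 0.01), and the replicate block across genotypes is given here alone.

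At day 18 the direct count (2) was 357 with DESeq2, 17 with non-targeting totals, 1 with limma, 22 with a replicate block, 0 with lane 3 reads subtracted in edgeR (1704 at an unadjusted p under 0.05) and 0 to 319 with 1 line left out. At day 0 the count (0) was 21 with DESeq2, 68 with non-targeting totals and 0 to 519 with 1 line left out. By day 4, WT (0) had 366 with DESeq2 and 1256 with limma, P95H (693) had 1314 with DESeq2, 2152 with limma, 1 with no replicate block and 10 with lane 3 reads subtracted, and the difference (0) had 1 with DESeq2. By day 11, WT (252) had 1492 with DESeq2, 1185 with non-targeting totals, 2853 with limma and 0 with no replicate block in edgeR (751 at an unadjusted p under 0.05), P95H (1767) had 3294 with limma and 83 with no replicate block, and the difference (0) had 42 with DESeq2. Leaving out the line as a replicate block changed no other count of genes. The core essential difference (-1.13) was -2.51 with lane 3 reads subtracted, -0.41 with log2 of CPM plus 1, -0.78 with the mean and -1.69 to -0.70 with 1 line left out. The value of -2.51 may depend on the floor at 0 reads. Lists passing went from 15 to 3 in WT, of which 2 are among the 15, and from 11 to 0 in the difference with an estimated correlation in camera, and the 11 ran from 3 to 13 with 1 line left out. Over the calls of single genes and lists, without the counts above, leaving out 1 line made 129 weaker and left 1385 the same, and the other settings made 660 weaker and left 2598 the same.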

Other observations

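Tests of the hypotheses in this part were chosen after the results were seen.

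Of 45 chromatin regulators 11 fell and 5 rose in WT (12 and 5 adjusted over the list alone), with Bap1 at -2.08 ± 0.41 and Kmt2c at 2.38 ± 0.42, and 18 fell and 6 rose in P95H (21 and 7 adjusted over the list alone), with the cohesin genes Smc1a at -4.47 and Stag2 at -4.41 and with Mllt10 at 1.46. Camera gave adjusted p of 0.282 in WT and 0.184 in P95H with an estimated correlation. Of 36 negative growth regulators and tumour suppressors 8 rose and 5 fell in WT (9 and 5 adjusted over the list alone) and 12 rose and 7 fell in P95H (14 and 7 adjusted over the list alone). The RAS regulator Lztr1 reached 1.95 in WT and 1.96 in P95H, the MAP kinase phosphatase Dusp6 reached 1.42 and 1.54, the mTORC1 inhibitor Tsc2 changed by -1.50 and -1.81 and the mediator subunit Med12 by -2.15 and -4.21. That list did not pass camera in either genotype (adjusted p = 0.214 and 0.365).

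Guides against mitochondrial complex I fell for 13 of 41 genes in WT (14 adjusted over the list alone) and 26 in P95H (28 adjusted over the list alone), with camera adjusted p of 0.186 and 0.0491 with an estimated correlation. For nonsense-mediated decay and the exon junction complex 9 of 18 fell in WT (12 adjusted over the list alone), with the cap-binding gene Ncbp1 at -2.23 and Smg8 at -2.27, and 12 in P95H (13 adjusted over the list alone), with Ncbp1 at -4.33 and Magoh at -3.53 (camera adjusted p = 0.0563 and 0.0187 with an estimated correlation). Of 21 G1/S inhibitors and RB family genes 2 rose and 1 fell in WT and 4 rose and 3 fell in P95H (4 and 2, then 4 and 3, adjusted over the list alone; camera adjusted p = 0.578 and 0.411). Olfactory receptor guides rose for 69 and fell for 20 of 1078 genes in WT, and rose for 91 and fell for 16 in P95H (27 and 4, then 40 and 4, adjusted over the list alone), with medians of 0.10 and 0.14 on the TMM scale. Sums of non-targeting guides had medians of 0.18 and 0.26, and relative to non-targeting guides the olfactory receptor guides changed by -0.13 and -0.15, so the direction turns with the reference. That list passed camera upward in P95H (adjusted p = 0.00567, and adjusted p = 0.000873 with an estimated correlation), and in WT only with an estimated correlation (camera adjusted p = 0.0842, and adjusted p = 0.0232 with an estimated correlation). Replication stress genes fell for 10 of 23 in WT (12 adjusted over the list alone; camera adjusted p = 0.0855 with an estimated correlation).

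A need for the spliceosome beyond the general loss of essential guides is a hypothesis that follows from the splicing role of Srsf2. The change of a list is here the median change of its genes' summed counts on the TMM scale, not relative to non-targeting guides. Divided by this change of core essential genes in the same line, the spliceosome change was 0.99 ± 0.20 in WT and 1.00 ± 0.02 in P95H (SD, n = 3 lines each), a difference of 0.0083 with an exact permutation p of 1. The spliceosome difference between genotypes may thus follow that of essential genes at large, though 3 lines against 3 leave it open.

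A need for G1/S activators beyond the general loss was tested in the same way. The relative change was 0.56 ± 0.19 in WT and 0.29 ± 0.13 in P95H (SD, n = 3 lines each), a difference of -0.26 towards a smaller relative loss in P95H, with an exact permutation p of 0.2. The lines are too few to exclude a larger need in P95H. Over the 20 lists the adjusted p of this measure was 1 for each, but with an exact p of at least 0.1 none could pass. Only nonsense-mediated decay and the exon junction complex reached an exact permutation p of 0.1. Its difference was -0.37, towards a smaller relative loss in P95H.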
